A study of Mus musculus with 2 samples.

How the data were processed

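Total RNA-seq was measured in 2 libraries of mouse bone marrow progenitors, 1 per biological replicate, both labelled megakaryocyte progenitor cell (CFU-Meg). CFU-Meg stands for the colony-forming progenitor of megakaryocytes, the cells that release platelets. Per the labels, the cells came from male C57BL/6J mice of 5 to 6 weeks, each library was started from 1 ng of RNA, and the size ranges of the libraries were 149 to 512 and 157 to 497. The 2 libraries come from separate biosamples under the same donor identifier, so the spread between them need not be the spread between animals. The gate used to sort the cells is described in protocol documents that were not used here.

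Per the file list deposited with each sample, the reads were aligned to mouse genome build mm10 and quantified against GENCODE annotation M4, each library on its own. The names of the columns are those that RSEM writes; the version of the quantifier, the aligner, the use of strand and the read layout are not given in the sources used here. Per the file headers, the deposited expected counts are estimated reads per gene or transcript, not normalized, in which a read that fits several features is divided among them. The authors' TPM values are relative transcript abundances scaled to a fixed total over every row, the spike-in and tRNA rows included. The deposited FPKM values are fragments per kilobase of effective length, scaled to the size of the library. The deposited score columns hold the bounds of the authors' credibility interval and the posterior SD, whose credibility level is not given in the sources used here. These bounds belong to the posterior mean, so the maximum likelihood TPM can lie outside them. The deposited percent values give the part of a gene's TPM assigned to each transcript. Because TPM has a fixed total, abundant ribosomal and mitochondrial RNA lowers the TPM of every other gene, and division by effective length makes the TPM of very short RNAs imprecise. Reads of near-identical copies, such as pseudogenes, and of overlapping antisense genes could not be told apart in these tables.

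The gene tables held 69691 rows, of which 43346 were Ensembl genes, 26248 had numeric identifiers and 97 were spike-in rows. The numeric rows took 28.6 and 10.0 expected counts in replicates 1 and 2. Symbols and positions were taken from GENCODE M21 on GRCm38, the assembly of mm10, and 42462 Ensembl rows (98.0%) had a match. Of the symbols in the fixed lists, 4 had no match (Diap1, Snhg1, Snhg8 and Rn18s) and were left out. Diap1 was written for Diaph1, so that gene was not analysed within its list.

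Expected counts totalled 82746658 in replicate 1 and 75652762 in replicate 2, of which 41115850 and 38000273 lay outside the mitochondrial, small RNA, spike-in and numeric rows and Gm42418. For the median megakaryocyte list member, 1 TPM was worth 116 reads. The TPM that 3 reads would give was computed for every gene as the limit that a count of 0 allows. It is no bound for a gene whose reads also fit other genes, since division can leave it an expected count of 0. The deposited interval is given for some of these genes, not for all. These limits and the binomial intervals cover counting error only, because PCR copies of a molecule are not independent.

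With 1 group, no test between conditions was possible. The agreement of the libraries was measured by Pearson's r and Spearman's rho of log2(TPM + 1) across Ensembl genes with a TPM of 1 or more in at least 1 library, and genes are not independent replicates. The biological coefficient of variation (BCV) was estimated with edgeR 4.0.16 in R 4.3.3 from expected counts rounded to whole numbers, with TMM scaling, an intercept-only design and the filterByExpr filter. Reads of each gene were compared between the libraries with an exact two-sided binomial test against the TMM library ratio with Benjamini-Hochberg adjustment, called at an adjusted p under 0.05 and an absolute log2 ratio of 1 or more. That test compares 2 libraries, not conditions.

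Gene lists for 10 blood and marrow lineages, 8 functions and 2 controls were fixed before the data were examined. The megakaryocyte surface and granule list was set against each other lineage list by the percent of gene pairs in which the megakaryocyte gene had the higher mean TPM, with ties shared equally. Its SD comes from the same percent in each library alone, which need not average to the percent from mean TPM. For each list, the median TPM was ranked among 10000 random lists of named genes. The median log2 ratio between the libraries, with a prior count of 2, was ranked among 10000 random lists matched on mean expression in 20 bins. The list shifts, like the binomial test, describe these libraries alone. Some megakaryocyte, erythroid, granulocyte, monocyte, dendritic and stem cell list members also stand in another list.

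Named genes followed a rule fixed before the data were examined: 14 key genes of these lineages, the 4 highest members and up to 2 members under 1 TPM of each list, the 10 most abundant genes outside mitochondrial, ribosomal and small RNA, and the 6 genes with the largest ratio in each direction past the library test with a mean TPM of 10 or more. Isoforms were named for key genes and Tubb1, Myh9 and Gfi1b where at least 2 transcripts took 10% or more in both libraries. Other genes were named after their values were seen, as members of the lists. The single values of some genes that the rule names are not reported here.

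The procedures were tested on simulated data. For replicate 2 against replicate 1, counts of 14304 genes drawn with a BCV of 0.2 gave 0.199. With counting noise and 200 changed genes of 20 to 20000 reads, 96% of the 3-fold and 100% of the 4-fold changes were called, and 1 unchanged gene was called. That simulation held no spread between replicates, so it does not show how many calls such spread would bring in the real libraries. For the list shifts, drawn from 19385 genes, a list raised by 1 on the log2 scale reached percentile 100, and 5 of 100 unchanged lists fell outside percentiles 2.5 to 97.5.

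Alternatives fixed before the data were examined covered DESeq2 1.42.0 size factors, total counts, filters on low values, FPKM, a pseudocount of 0.1, posterior mean estimates, values without length scaling, other denominators and each library alone. Alternatives added later used a denominator without Gm42418, random lists of protein-coding genes, the megakaryocyte list without 5 members that other blood cells share, and 2 groups of granule genes. Groups of erythroid progenitor, globin, progenitor surface and immunoglobulin genes were also chosen after the values were seen. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.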

Results

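The transcriptome of cells labelled megakaryocyte progenitor (CFU-Meg), from male C57BL/6J mice, was measured by total RNA-seq in 2 libraries. Replicate 1 held 82746658 and replicate 2 held 75652762 expected counts. A TPM of 1 or more was reached by 11905 genes in replicate 1, by 11561 in replicate 2 and by 11114 in both. The labels give 1 group and no contrast, so the comparisons are between gene programmes within the libraries and between the replicates. Values are mean TPM ± SD (n = 2) unless stated otherwise, and positions are on GRCm38.

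Megakaryocyte surface and granule genes were low in the libraries labelled megakaryocyte progenitor. The median of their list was 0.60 TPM, with 0.83 in replicate 1 and 0.43 in replicate 2. Of the 25 members, 7 reached 1 TPM in both libraries, 14 lay under 1 TPM in both and 3 were listed at 0 in both. Itga2b (ENSMUSG00000034664.9, chromosome 11, 102453297 to 102470122), which encodes the integrin CD41 that marks this lineage, stood at 2.41 ± 0.32 TPM. Its partner Itgb3 stood at 0.88 ± 0.07 TPM.

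Other platelet genes had similarly low values. Pf4, a chemokine of platelet granules, had 0.60 ± 0.47 TPM from expected counts of 26 and 7. Vwf, the platelet adhesion protein, had 1.04 ± 0.04 TPM. Gp1bb, a subunit of its platelet receptor, had an expected count of 0 in replicate 1, with a deposited credibility interval of 0.0020 to 0.185 TPM, and stood at 0.30 TPM in replicate 2. Tubb1, the tubulin of platelets, had an expected count of 0 in both libraries, which allows up to 0.038 TPM in replicate 1 and 0.041 TPM in replicate 2. The 3 highest members were Rgs18 at 39.5 ± 2.1 TPM, Cd9 at 18.98 ± 2.79 TPM and Plek at 11.9 ± 1.5 TPM, which other blood cells also express. The list median lay at percentile 98.2 of random lists of named genes and at percentile 50.5 of random lists of protein-coding genes, a background chosen after the values were seen.

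Of the 10 lineage lists, granulocyte genes had the highest median. All 18 members of their list reached 1 TPM in both libraries, with a median of 199 TPM (161 in replicate 1 and 238 in replicate 2), at percentile 100 of random lists. Mpo, the myeloperoxidase of primary granules (ENSMUSG00000009350.9, chromosome 11, 87793581 to 87804413), stood at 5892 ± 586 TPM. The granule proteases Elane and Ctsg stood at 3210 ± 637 and 1849 ± 157 TPM. S100a8, a calcium-binding protein of neutrophils and monocytes, stood at 1845 ± 752 TPM. A megakaryocyte gene was higher than a granulocyte gene in 2.2% ± 0.2 of 450 gene pairs (SD over the libraries, n = 2), with 2.7% in replicate 1 and 2.4% in replicate 2.

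Erythroid genes were also higher than megakaryocyte genes. Their list had a median of 7.32 TPM, and 18 of 24 members reached 1 TPM in both libraries. The carbonic anhydrases Car1 and Car2 stood at 377 ± 191 and 88.5 ± 34.2 TPM, the transferrin receptor gene Tfrc at 51.5 ± 7.6 TPM, and the erythroid regulator Klf1 at 7.19 ± 2.96 TPM. The alpha globin gene Hba-a2 stood at 16.7 ± 8.3 TPM, Epor at 1.86 ± 0.84 TPM, Slc4a1 at 0.66 ± 0.27 TPM and Alas2 at 0.40 ± 0.15 TPM. The near-identical copies Hba-a1 and Hba-a2 share reads, so their separate values are uncertain, as are those of Hbb-bs and Hbb-bt. The megakaryocyte gene was the higher in 18.8% ± 0.3 of 600 pairs (n = 2).

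Monocyte genes and mast cell, basophil and eosinophil genes stood above the megakaryocyte genes as well. Among monocyte and macrophage genes, with a median of 7.46 TPM (4.76 in replicate 1 and 10.4 in replicate 2), Ly6c2, which can share reads with its close paralog Ly6c1, reached 2944 ± 250 TPM, Ms4a6c 84.7 ± 17.2 TPM, the regulator Irf8 41.4 ± 11.1 TPM and the chemokine receptor gene Ccr2 36.7 ± 7.9 TPM. The macrophage complement genes C1qa and C1qb lay at 0.16 ± 0.09 and 0.18 ± 0.20 TPM. In the mast cell, basophil and eosinophil list, with a median of 3.50 TPM, the carboxypeptidase gene Cpa3 stood at 52.1 ± 1.3 TPM, Mcpt8 at 38.6 ± 7.9 TPM, Prg2 at 24.3 ± 9.2 TPM and Hdc at 21.7 ± 1.0 TPM. The mature mast cell protease genes Mcpt4 and Tpsb2 had an expected count of 0 in both libraries, which allows up to 0.061 and 0.055 TPM in replicate 2. The megakaryocyte gene was the higher in 26.4% ± 0.3 of pairs with the monocyte list and in 37.3% ± 0.5 with the mast cell list (n = 2).

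Against stem cell and multipotent progenitor genes (median 0.99 TPM, with 1.52 in replicate 1 and 0.78 in replicate 2), the megakaryocyte gene was the higher in 36.9% ± 4.9 of pairs (n = 2). Cd48 stood at 104 ± 12 TPM and Cd34 at 78.3 ± 6.6 TPM, Gcnt2 and Hlf at 8.99 ± 3.38 and 7.79 ± 0.64 TPM, and Flt3 at 4.77 ± 1.53 TPM, while the stem cell markers Procr and Slamf1 lay at 0.18 ± 0.25 and 0.31 TPM. Against dendritic cell genes (median 1.06 TPM) the share was 37.7% ± 8.5, and the antigen presentation genes H2-Ab1, Cd74 and H2-Aa stood at 21.5 ± 3.3, 18.4 ± 10.4 and 14.0 ± 2.3 TPM. Siglech and Ccr9 lay at 0.02 ± 0.03 and 0.26 ± 0.09 TPM, and Bst2 at 5.82 ± 1.31 TPM. The Siglech values lay below its deposited credibility intervals, 0.036 to 0.188 TPM in replicate 1 and 0.070 to 0.251 TPM in replicate 2, so its level is uncertain.

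Genes of lymphocytes and marrow stroma lay lowest. The B cell list had a median of 0.19 TPM (0.10 in replicate 1 and 0.18 in replicate 2), with Cd79b at 20.5 ± 1.5 TPM as its exception, Rag2 at 1.06 ± 0.50 TPM, and Cd79a at 0.20 ± 0.07 TPM. The T and NK cell list had a median of 0.24 TPM (0.34 in replicate 1 and 0.13 in replicate 2), with Nkg7 at 339 ± 18 TPM as its exception, Tcf7 at 0.81 ± 0.37 TPM, Lck at 0.79 ± 0.41 TPM and an expected count of 0 for Cd3e in both libraries, which allows up to 0.040 TPM in replicate 2. Stroma and endothelium genes had a median of 0.02 TPM (0.02 in replicate 1 and 0.0 in replicate 2), the highest being Pdgfrb at 2.13 ± 0.66 TPM and Flt1 at 1.09 ± 0.27 TPM, and the endothelial gene Cdh5 had an expected count of 0 in both libraries, which allows up to 0.014 TPM in replicate 2. The megakaryocyte gene was the higher in 66.7% ± 1.3, 64.5% ± 3.8 and 75.1% ± 0.2 of pairs with these 3 lists (n = 2). Among members of 1 TPM or more, the B cell value turned to 40.9%.

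**Figure D1:**
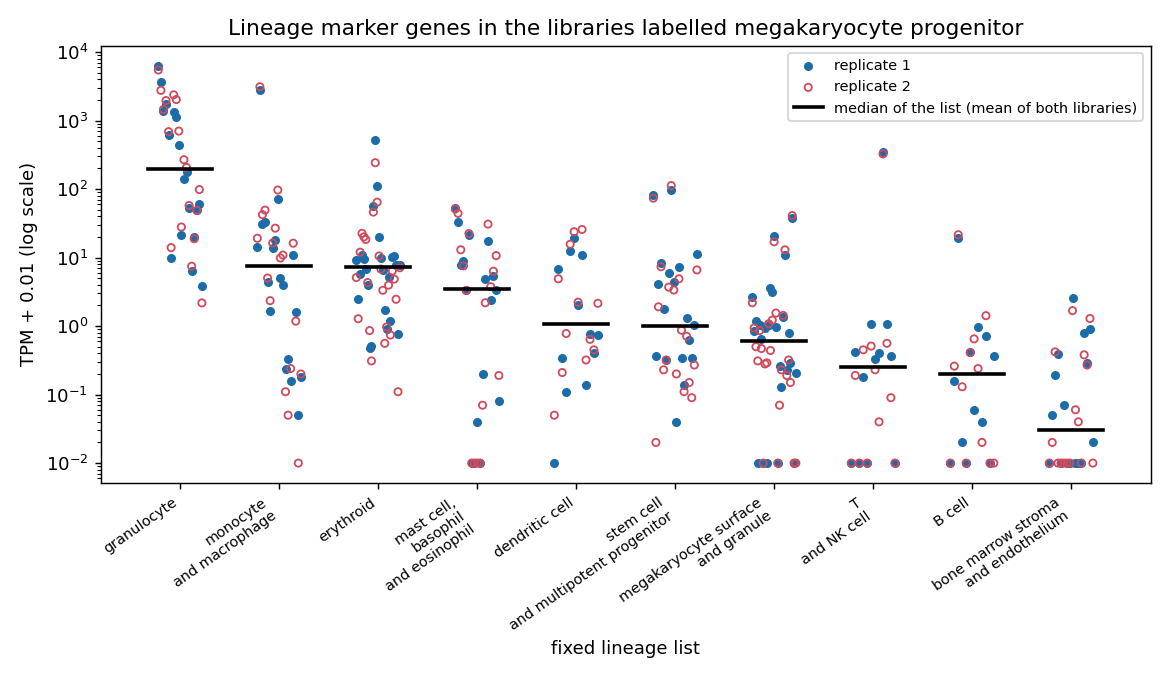
TPM + 0.01 on a log scale for each member of the 10 lineage lists, with filled points for replicate 1, open points for replicate 2 and a black line at the list median of mean TPM. The granulocyte median lies at 199 TPM and the megakaryocyte median at 0.60 TPM.

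Regulators of blood development were expressed throughout. All 25 transcription factors reached 1 TPM in both libraries, with a median of 24.2 TPM. Myb, Lmo2, Spi1 and Ikzf1 were the highest at 296 ± 33, 186 ± 13, 86.36 ± 15.98 and 64.9 ± 1.0 TPM. Of the factors among the key genes, Nfe2 stood at 52.4 ± 7.1 TPM, Runx1 at 42.6 ± 0.4 TPM, Fli1 at 35.9 ± 4.1 TPM, Gata1 at 7.64 ± 4.48 TPM and Gata2 at 5.98 ± 1.94 TPM. Cytokine receptor and JAK-STAT genes had a median of 12.1 TPM, led by the stem cell factor receptor Kit at 58.8 ± 7.5 TPM and the colony-stimulating factor receptor genes Csf3r at 48.8 ± 0.2 TPM, Csf2ra at 40.7 ± 3.0 TPM and Csf2rb at 20.4 ± 1.4 TPM. Of the feedback inhibitors, Socs2 lay at 0.21 ± 0.30 TPM and Socs3 at 0.36 ± 0.05 TPM.

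Genes of proliferation were high. All 20 DNA replication genes reached 1 TPM in both libraries, with a median of 39.3 TPM, and Pcna, Mcm3, Mcm6 and Mcm7 stood at 332 ± 16, 271 ± 8, 138 ± 0.1 and 101 ± 3 TPM. All 20 mitosis genes did too, with a median of 40.5 TPM, and Mki67, Top2a, Ube2c and Birc5 stood at 161 ± 5, 117 ± 1, 114 ± 2 and 78.3 ± 5.7 TPM. The platelet cytoskeleton list had a median of 51.8 TPM, led by the widely expressed Actb at 1424 ± 81 TPM, Cfl1 at 764 ± 17 TPM, Actg1 at 702 ± 58 TPM and Pfn1 at 470 ± 44 TPM, while Myl9 lay at 0.04 ± 0.06 TPM. Heme and iron genes had a median of 17.4 TPM, with the ferritin genes Ftl1 and Fth1 at 640 ± 42 and 480 ± 14 TPM, and Alas1 at 191 ± 3 TPM. Immediate early and heat shock genes had a median of 16.5 TPM, with Hspa8 at 1441 ± 138 TPM, Hsp90aa1 at 549.7 ± 1.7 TPM, Zfp36 at 68.6 ± 26.8 TPM and Fos at 49.4 ± 14.9 TPM. Interferon response genes had a median of 2.66 TPM, with Ifitm3 at 72.4 ± 15.4 TPM, Ifitm1 at 30.5 ± 9.2 TPM, Ifi27 at 29.2 ± 5.3 TPM, Isg15 at 0.68 ± 0.25 TPM and Ifit1 at 0.74 ± 0.16 TPM. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d stood at 40.5 ± 1.5, 15.7 ± 1.2, 12.1 ± 2.1 and 5.71 ± 1.73 TPM, while Xist lay at 0.19 ± 0.18 TPM and Tsix at 0.02 ± 0.03 TPM, and the sex-linked list had a median of 8.89 TPM.

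Mitochondrial RNA and the single gene Gm42418 took a large part of both libraries. Gm42418 (ENSMUSG00000098178.1, chromosome 17, 39846958 to 39848788, plus strand), annotated as a lincRNA, held 22.1% ± 1.8 of expected counts (n = 2), and 68.0% of its length overlaps the 18S-related locus Rn18s-rs5 of RefSeq on GRCm38.p6. Mitochondrial rRNA genes held 22.6% ± 1.2 and other mitochondrial genes 5.18% ± 0.30. Protein-coding genes other than ribosomal protein and histone genes held 43.6% ± 0.3 and ribosomal protein genes 3.86% ± 0.09. Spike-in rows held 0.003% of expected counts, from 2539 and 2222 reads. Among single genes outside the mitochondrial, ribosomal protein and small RNA classes, Gm42418 was followed by the elongation factor gene Eef1a1 at 8446 ± 19 TPM, and Mpo, Elane, Ly6c2 and Ptma (2581 ± 67 TPM) were among the first 10. The pseudogenes Gm10222, Gm29216, Gm28661 and Gm28437, side by side on chromosome 1 between 24612407 and 24616197, ranked with them at 6588 ± 104, 6133 ± 314, 4533 ± 30 and 3891 ± 2 TPM. They resemble mitochondrial sequence and can share reads with it, which was not tested. The deposited credibility intervals were wide for Gm28661 and Gm28437, the latter at 1100 to 4766 TPM in replicate 1, and narrow for Gm10222 and Gm29216. Abundant non-coding RNAs had a list median of 73.5 TPM, with Rn7sk at 5664 ± 631 TPM, Rpph1 at 1323 ± 185 TPM, Gas5 at 831 ± 166 TPM, Malat1 at 522 ± 120 TPM, and Terc at 0.26 ± 0.28 TPM. Meg3 had an expected count of 0 in both libraries, with deposited credibility intervals of 0.087 to 0.433 and 0.093 to 0.463 TPM. Other genes with an expected count of 0 in both libraries also had lower bounds clearly above 0. In replicate 1 the intervals were 0.295 to 1.14 TPM for Pax5 and 0.042 to 0.332 TPM for Col3a1. Such bounds therefore do not show that Meg3 was expressed.

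**Figure D2:**
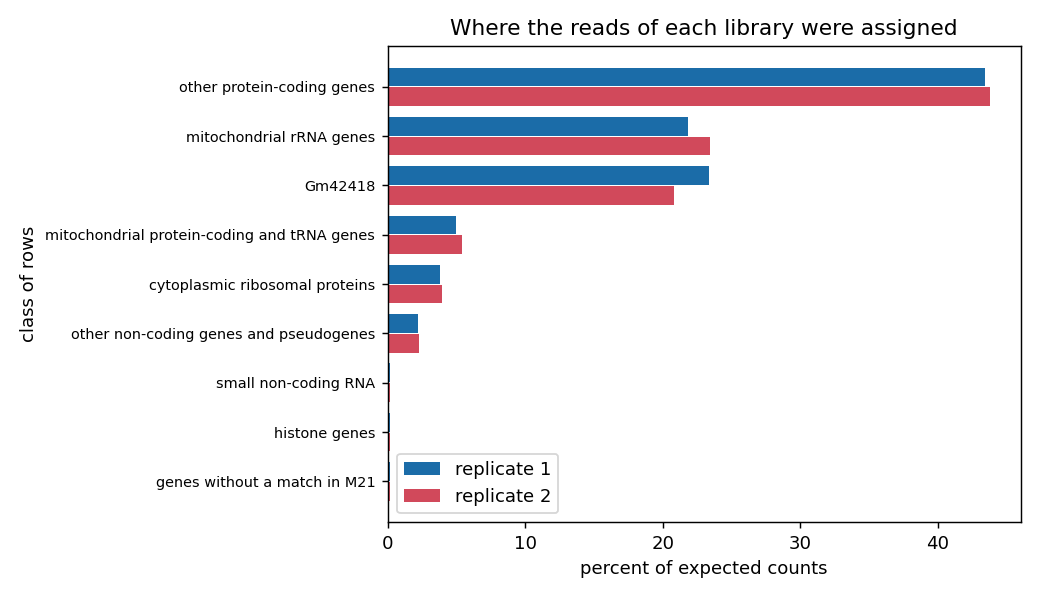
Percent of expected counts assigned to the 9 largest classes of gene rows, with 1 bar per library and no error bar. Gm42418 and the mitochondrial rRNA genes have means of 22.1% and 22.6%, against 43.6% for the other protein-coding genes.

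The replicates gave closely similar values for abundant genes and not for rare ones. Across 12352 genes, Pearson's r of log2(TPM + 1) was 0.964 and Spearman's rho 0.962, and the BCV was 0.209 over 14304 genes. The median absolute log2 ratio was 0.10 for genes of 100 TPM or more, 0.14 from 10 to 100 TPM, 0.30 from 1 to 10 TPM and 1.07 from 0.1 to 1 TPM, where 51.7% of genes differed by more than 2-fold. Most megakaryocyte list members lie in that lowest range. The libraries differed by more than counting noise, with a chi-square of 41.9 per gene, so they are not copies of 1 library. That value does not show that they come from separate animals.

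Reads of 1096 of 14304 genes differed at an absolute log2 ratio of 1 or more, 721 higher in replicate 1 and 375 higher in replicate 2, by the exact binomial test with Benjamini-Hochberg adjustment. Among genes of 10 TPM or more on average, 35 of 5740 differed, 15 higher in replicate 1 and 20 higher in replicate 2. Higher in replicate 1 were the pseudogene Gm12671 (5.77-fold), the blood group gene Kel (2.45-fold), the sodium pump subunit gene Atp1b2 (2.22-fold), the metallothionein gene Mt2 (2.07-fold) and the small RNA genes Gm23946 (3.63-fold) and Gm26444 (2.07-fold). Higher in replicate 2 were the beta globin gene Hbb-bs and the immunoglobulin kappa gene Igkc (both 3.07-fold), the pseudogene Gm7846 (3.56-fold) and the small RNA genes Gm23262 (4.88-fold), Gm25679 (4.0-fold) and Gm22767 (3.78-fold). The deposited credibility intervals of Gm12671, at 19.6 to 47.2 TPM in replicate 1 and 1.36 to 39.7 TPM in replicate 2, overlap, so its fold is uncertain. Gm25679 and Gm26444 lie near each other on chromosome 12 and had equal TPM in replicate 1 with wide credibility intervals, so reads shared between copies make them uncertain. The same test called 520 genes with counts divided by 4, and 3382 of 19635 genes with no filter.

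Several gene groups stood apart between the libraries. Relative to replicate 1, replicate 2 had lower erythroid genes (median log2 ratio -0.52, lower in 16 of 24, percentile 0.0 of matched random lists) and lower stem cell and multipotent progenitor genes (-0.68, lower in 15 of 18, percentile 0.1). Car1 and Car2 had log2 ratios of -1.03 and -0.76, Klf1 -0.82, Gata1 -1.23 and Flt3 -0.63. Within the erythroid list the 4 globin genes went the other way, at 1.11 to 1.62, as did Slc4a1 at 0.89. Replicate 2 had higher immediate early and heat shock genes (0.78, higher in 17 of 18, percentile 100), with Zfp36 at 0.86, Fos at 0.69 and Jun at 0.77. It had higher monocyte and macrophage (0.43, 14 of 18, percentile 100), granulocyte (0.23, 14 of 18, percentile 100) and dendritic cell genes (0.42, 9 of 12, percentile 99.3). Mpo, Elane and the neutrophil chemokine receptor gene Cxcr2 went the other way within the granulocyte list, at -0.16, -0.36 and -0.61, while S100a8 stood at 0.92.

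Smaller shifts outside the central 95% of matched lists were found for mast cell, basophil and eosinophil genes (0.20, percentile 97.6), platelet cytoskeleton genes (0.18, percentile 99.2), transcription factors (-0.10, percentile 1.0), heme and iron genes (-0.12, percentile 1.6) and abundant non-coding RNAs (-0.16, percentile 0.2). The megakaryocyte list lay inside (-0.16, lower in 13 of 22, percentile 31.4), as did the B cell (0.20, percentile 80.7), T and NK cell (-0.70, percentile 9.5), stroma (-0.56, percentile 19.7), cytokine receptor (-0.08, percentile 14.0), DNA replication (-0.01, percentile 13.3), mitosis (0.06, percentile 66.4), interferon (-0.22, percentile 5.9) and sex-linked lists (-0.28, percentile 5.6). With 20 lists, 1 would be outside by chance if list members varied independently. Genes of the same programme may vary together, and some lists share members, so more could fall outside by chance. These percentiles describe the 2 libraries, and n = 2 does not separate them from the spread between animals or preparations.

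**Figure D3:**
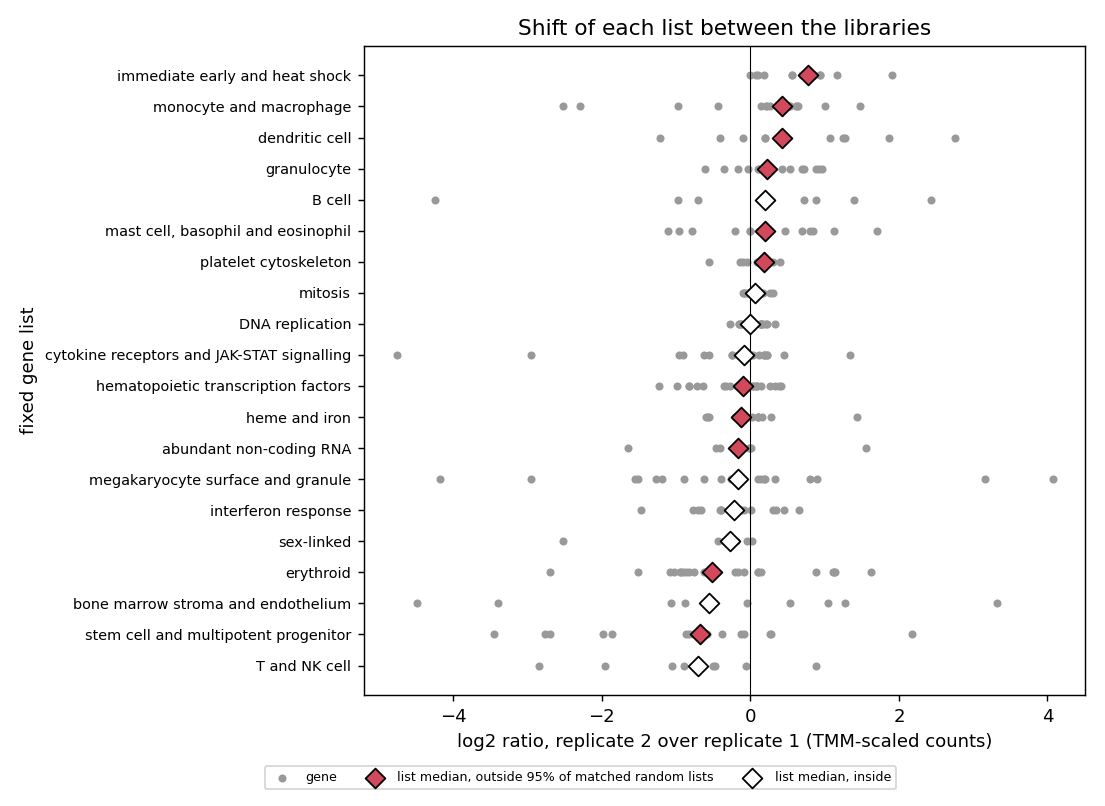
Log2 ratio of TMM-scaled counts, replicate 2 over replicate 1, for each fixed gene list, with a grey point per gene and a diamond at the list median, red where it lay outside 95% of matched random lists. The erythroid and stem cell medians lie at -0.52 and -0.68, and the immediate early and heat shock median at 0.78.

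Isoform shares differed little between the libraries for Mpo and more for Kit, Gata2 and Itga2b. For Mpo, the protein-coding transcripts ENSMUST00000121303.3 and ENSMUST00000146650.1 took 60.8% ± 0.2 and 35.3% ± 0.0 of the gene's TPM (n = 2). A protein-coding transcript led Runx1 (ENSMUST00000023673.9, 45.1% ± 2.5), whose processed ENSMUST00000189679.1 took 23.8% in replicate 1 and 16.8% in replicate 2, and Gfi1b (ENSMUST00000028156.7, 85.9% ± 3.8). For Kit, the protein-coding ENSMUST00000144270.3 took 43.6% in replicate 1 and 59.7% in replicate 2 and ENSMUST00000005815.6 took 51.0% and 32.4%. Their credibility intervals overlapped in replicate 1 and not in replicate 2, where the first was the higher. For Gata2, the protein-coding ENSMUST00000015197.7 had the larger share at 68.4% ± 15.4, with 79.3% in replicate 1 and 57.5% in replicate 2. In replicate 2 its credibility interval overlapped that of ENSMUST00000170089.3 (1.49 to 3.35 against 1.16 to 3.08 TPM), so their order is not resolved there. Transcripts annotated as processed led for Myh9 (ENSMUST00000124844.3, 56.6% ± 7.1) and Vwf (ENSMUST00000146264.1, 47.1% in replicate 1 and 52.8% in replicate 2). The processed Myh9 transcript is 720 bases long, against 7433 for the protein-coding ENSMUST00000016771.8 (41.4% ± 6.8). Shares of TPM are not shares of reads, since TPM is divided by length. For Itga2b, the processed ENSMUST00000134735.1 took 16.1% in replicate 1 and 44.1% in replicate 2 and the protein-coding ENSMUST00000103086.3 took 23.9% and 31.9%. Their credibility intervals overlapped in both libraries, so their order is not resolved. The Itga2b and Vwf values rest on transcripts under 1 TPM.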

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

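The choices with Gm42418 left out of the total, random lists of protein-coding genes and the megakaryocyte list without shared members were made after the results were seen, as were the granule gene groups; the others were fixed before the data were examined. No paired analysis was possible because there is 1 group. The correlation, the BCV and the read comparison have no value without a replicate. The cause was not tested for the differences below, except where the construction of the alternative gives it. Most megakaryocyte members lie where the median absolute log2 ratio was 1.07, which holds counting error together with the spread between the libraries.

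The direction against 50% was kept in the alternatives of the megakaryocyte comparisons fixed before the data were examined except that with B cell genes among members of 1 TPM or more, which reversed to 40.9%. With that filter the shares were 27.7% for erythroid, 5.1% for granulocyte, 19.6% for monocyte, 19.8% for mast cell, 28.8% for dendritic cell and 59.1% for stroma genes. Without length scaling they were 2.9% for granulocyte, 27.6% for monocyte, 39.9% for mast cell, 71.5% for B cell and 71.1% for stroma genes. With posterior means they were 18.3% for erythroid, 2.4% for granulocyte, 27.3% for monocyte, 62.5% for B cell and 71.9% for stroma genes. Leaving out the shared members (Cd9, Plek, Rgs18, Selp and Thbs1), the 3 highest among them, on the megakaryocyte side alone lowers the share by construction, to 8.4% for erythroid and 0.0% for granulocyte genes, and says nothing about stability. Each library alone gave 19 to 19.4% for erythroid, 2.4 to 2.7% for granulocyte, 27.1 to 27.6% for monocyte, 36.1 to 36.8% for mast cell, 65.7 to 67.5% for B cell, 61.7 to 67.0% for T and NK cell, 32.8 to 44.8% for dendritic cell, 34.0 to 41.0% for stem cell and 74.8 to 75.0% for stroma genes.

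Rescaled TPM multiplies every list alike by construction, by 1.59 without mitochondrial, small RNA and spike-in rows and by 2.12 without Gm42418 and mitochondrial rows. The medians became 0.95 and 1.29 for megakaryocyte, 11.6 and 15.6 for erythroid, 318 and 422 for granulocyte, 11.9 and 15.8 for monocyte, 5.54 and 7.44 for mast cell, 0.30 and 0.40 for B cell, 0.38 and 0.52 for T and NK cell, 1.70 and 2.25 for dendritic cell, 1.57 and 2.11 for stem cell and 0.04 and 0.05 for stroma genes. They became 38.5 and 51.4 for transcription factors, 19.2 and 25.6 for cytokine receptors, 82.4 and 110.0 for platelet cytoskeleton, 62.4 and 83.4 for DNA replication, 64.5 and 86.0 for mitosis, 26.4 and 35.1 for immediate early, 4.23 and 5.66 for interferon, 27.6 and 37.0 for heme and iron, 14.1 and 18.9 for sex-linked genes and 117 and 156 for abundant non-coding RNAs. Against random protein-coding lists, 5 lists no longer stood above the central 95%: megakaryocyte at 50.5, monocyte at 96.9, mast cell at 83.9, interferon at 75.7 and sex-linked at 88.4; 15 stayed on their side.

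Pearson's r was 0.912 with a pseudocount of 0.1, 0.989 over all gene rows, 0.953 from 10 TPM, 0.968 with FPKM and 0.976 without mitochondrial, ribosomal protein and small RNA rows. The BCV was 0.384 without a filter. The read comparison called 3382 genes without a filter, where more low genes are tested, and 520 with counts divided by 4. At 10 TPM, 5509 genes were detected in both libraries. At 1 TPM, each library alone gave 11561 to 11905. Size factors or a filter at 5 TPM kept 36 of 37 list shifts on their side of the central 95%; interferon genes moved outside it at 5 TPM, to -0.39. As shares of TPM instead of counts, the classes differed by construction, from 17.2% to 22.1% for Gm42418, 8.65% to 3.86% for ribosomal proteins, 0.123% to 0.119% for unmatched genes, 0.423% to 0.136% for histones, 8.86% to 5.18% for mitochondrial protein and tRNA genes, 26.8% to 22.6% for mitochondrial rRNA, 0.001% to 0.0% for numeric rows, 5.16% to 2.23% for other non-coding genes and pseudogenes (immunoglobulin genes included), 31.3% to 43.6% for other protein-coding genes, 1.17% to 0.142% for small RNA, 0.292% to 0.007% for snoRNA and 0.006% to 0.003% for spike-in rows. Posterior means gave 44.5% for the leading Vwf transcript and 79.5% for that of Gfi1b, and the 6 other leading transcripts differed by less than the SD.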

Other observations

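The gene groups and the tests of explanations in this part were chosen after the results were seen, except the percentiles and shares of the fixed lists. Genes of secondary granules with the S100 genes were higher in replicate 2 in 8 of 8 (median log2 ratio 0.79, percentile 100 of matched random lists), with Camp at 0.96, Chil3 at 0.93, S100a9 at 0.89 and Ngp at 0.70. Genes of primary granules lay inside the matched lists (0.15, 5 of 8 higher, percentile 91.0), with Prtn3 at 0.11 and Srgn at 0.26. The difference between the groups was not tested, and members overlap, with Lcn2 at 0.25 and Mmp8 at 0.26 in the first and Serpinb1a at 0.30 in the second.

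Surface genes used to sort marrow progenitors had high values for Fcgr3 (166 ± 11 TPM), Cd34 (78.3 ± 6.6 TPM), Fcgr2b (59.1 ± 1.2 TPM) and Kit (58.8 ± 7.5 TPM), SD with n = 2. Eng stood at 6.26 ± 0.17 TPM, Ly6a at 3.03 ± 1.59 TPM, Itga2b at 2.41 ± 0.32 TPM, Slamf1 at 0.31 TPM and Il7r at 0.22 ± 0.19 TPM. Of the immunoglobulin genes, Ighm stood at 103 ± 2 TPM, Igkc at 15.6 ± 11.0 TPM and Ighd at 0.73 ± 0.40 TPM.

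The first pattern was high granulocyte and low megakaryocyte genes under a megakaryocyte progenitor label. Length scaling is argued against, since the megakaryocyte gene was the higher in 2.9% of pairs with granulocyte genes without it. Granulocyte RNA added to a sample mainly of cells with an active megakaryocyte programme is argued against by the megakaryocyte list as a whole. Its median was 0.60 TPM (0.83 in replicate 1 and 0.43 in replicate 2). Of its 25 members, 14 lay under 1 TPM in both libraries and 7 reached 1 TPM in both. A mixture with a small share of such cells was not decided. The erythroid genes stood above the megakaryocyte genes too, with the megakaryocyte gene higher in 18.8% of pairs. That would speak against such a mixture only if neither cell type brought erythroid RNA, which was not tested. A label or sort gate that names another cell type stays open as a candidate explanation. The granulocyte gene was the higher in at least 84.0% of pairs with each other lineage list, which restates the pattern and adds no support of its own. Progenitors that have not yet turned on platelet genes also stay open, for the low megakaryocyte genes only. That state alone would not account for the granulocyte list, whose median was 199 TPM (161 in replicate 1 and 238 in replicate 2). The design holds no other cell type, and no biological explanation was tested.

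The second pattern was lower erythroid progenitor genes in replicate 2 (median log2 ratio -0.85, lower in 11 of 12, percentile 0.0) with higher globin genes (1.13, higher in 4 of 4, percentile 100). Beside them, Igkc (1.62), Ighd (1.16), Camp (0.96), S100a8 (0.92) and immediate early and heat shock genes (0.78) were higher. The more abundant Ighm had similar TPM in both libraries, and the B cell list lay inside its matched random lists (0.20, percentile 80.7). The erythroid progenitor and globin groups were chosen for the pattern. The first pair of tests used the fixed erythroid list, which also holds the globin genes and genes such as Car1 and Klf1. Those tests therefore use the values that showed the pattern and are not independent of it. Library scaling is argued against for that list, since 1 factor would move its matched random lists alike and it lay at percentile 0.0. A different amount of 1 kind of erythroid cell as the whole cause is argued against, since 4 of the 24 members, the globin genes in 2 pairs of near-identical copies, lay above the central 95% of genes of like expression and 5 lay below it, Klf1 at its bound. A larger share of early progenitors in replicate 1 cannot be told apart from other causes: the stem cell list lay at percentile 0.1, but the megakaryocyte list at percentile 31.4.

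The third pattern was the high share of Gm42418. Reads of 18S ribosomal RNA assigned to an annotated copy may account for it, since 68.0% of the gene overlaps the 18S-related locus of RefSeq. RefSeq also lists Gm42418 among the synonyms of that locus, Rn18s-rs5. The reads themselves were not analysed here, and no biological explanation was tested.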
